A study of Mus musculus with 28 samples.

How the data were processed

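RNA of sorted mouse bone marrow cells was measured on 28 Affymetrix expression arrays with 22690 probe sets each. Per the labels, each sample held about 10000 sorted cells, whose RNA was amplified and biotin-labelled. The arrays form 2 experiments, which the series' design text calls noncomparable because their RNA was amplified on different days, so the size of levels was not compared between them. What was set side by side is whether a probe set lay above the floor or median of its own experiment, and changes within each experiment. In the transduced experiment, granulocyte-macrophage progenitors (GMP) expressed the green fluorescent protein GFP (3 arrays) or the fusion MLL-AF9 (3 arrays). In the sorted experiment, normal marrow was sorted into a fraction enriched for haematopoietic stem cells (HSC, 5 arrays), common myeloid progenitors (CMP, 4 arrays), GMP (4 arrays) and megakaryocyte-erythroid progenitors (MEP, 3 arrays), and leukaemic cells with the sort markers of GMP (L-GMP, 6 arrays) were taken alongside. Group and replicate number came from the sample titles. Nothing in the labels says that replicates were separate animals, so the p-values measure the spread between samples, which may be technical.

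The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes, which give no version or scaling target. Each array held between 187 and 413 values at or below 0, which the MAS5 signal alone does not give, and the sources used here do not state how they arose. Array medians of the deposited values lay between 247 and 267 in the transduced experiment and between 90.8 and 116 in the sorted experiment. Scaling every array to a common level removes any change in total RNA per cell, and values near background have no reliable order. The log2 ratio of 3' to 5' signal over the Actb and Gapdh control probe sets, a measure of RNA length after amplification, averaged 1.49 ± 0.26 (SD, 6 arrays) in the transduced and 2.98 ± 0.18 (SD, 22 arrays) in the sorted experiment, and in L-GMP it was 2.85 ± 0.08 (SD, 6 arrays). A high ratio lowers the signal of probe sets far from the 3' end of their transcript. The number of arrays per group, between 3 and 6, limits the precision of every comparison.

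Within each experiment, every array was scaled to the common mean of its values after trimming 2% at each end, with factors between 0.923 and 1.12. Values below the 25th percentile of the experiment were set to that floor, which was 78.0 in the transduced and 38.7 in the sorted experiment (6.29 and 5.27 on the log2 scale), and all values were then taken to log2. A probe set was kept when it exceeded the median of the experiment on at least 3 arrays, which left 11524 probe sets in the transduced and 13439 in the sorted experiment. The 64 control probe sets were left out. The platform annotation named 1 gene for 20393 probe sets, several genes for 691 and none for 1555, and those that named several or none were not tested. Of the probe sets with 1 gene, 20364 had a symbol found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols were updated. No position is given, since expression probe sets were not mapped to a genome here. Each gene was represented by its kept probe set of highest mean, giving 7235 genes in the transduced and 8422 in the sorted experiment, of which 6865 were tested in both. Between 0 and 3.29% of the tested values of an array lay at the floor. Where all arrays of a group were at the floor, a fold change was computed against the floor and is given as a lower bound ("at least"). Where only some arrays of the lower group were at the floor, the fold and the log2 change are also no larger than without a floor, and "at least" is used where that held for most arrays of the group.

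Groups were compared with the moderated test of limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. The 6 transduced arrays were fitted on their own, and all 22 sorted arrays shared 1 fit with 9 contrasts. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Errors on log2 changes are standard errors (SE) of the fit and errors on levels are standard deviations (SD). A replicate number was treated as a pair when arrays of different groups with the same number stayed correlated above 0.1 after removal of group means. That held for 3 of the 3 pairs of the transduced experiment (r from 0.379 to 0.596 across genes, which are not independent replicates) and for 18 of the 37 pairs of the sorted experiment (r from -0.493 to 0.528). Arrays with different numbers also correlated in the transduced experiment, at 0.474 for replicate 3 of GFP with replicate 2 of MLL-AF9 and 0.192 for replicate 2 of GFP with replicate 3 of MLL-AF9, so only replicate 1 was set apart by its number. The transduced comparison is given also with the replicate pair as a block.

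The 25 gene lists covered HoxA genes and cofactors, other targets of MLL fusions, stem cell genes, lymphoid priming, primary granules, secondary granules, monocytes and macrophages, erythroid cells, megakaryocytes, mast cells with basophils and eosinophils, T and NK cells, B cells, dendritic cells with MHC class II, stroma and endothelium, S phase, G2 and M phase, cyclin-dependent kinase inhibitors, MYC targets with ribosome biogenesis, WNT signalling, immediate early and stress genes, interferon-stimulated genes, glycolysis, ribosomal proteins, sort markers and sex-linked genes. Of these, 24 were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted over the 24 lists of a comparison. For sex-linked genes only Xist passed the filter. The lists overlap: Bst2, Cdkn1c, Flt3, Gata2, Ighm, Klf4, Ldha, Myc, Pax5, Satb1, Tal1 and Vwf each stand in 2 of them.

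Stem cell program genes were those higher in HSC than in GMP, CMP and MEP at an adjusted p under 0.05 in all 3 contrasts. Their overlap with genes higher in L-GMP than in GMP was set against the product of the list sizes over the number of genes tested. Because both contrasts use the GMP arrays, it was repeated with the GMP arrays split between the contrasts and with a list defined without GMP. It was also repeated on 100 simulated data sets in which L-GMP did not differ from GMP. There 0.08 genes on average were called in L-GMP against GMP and the overlap was 0 in each set. That outcome follows from the setting, so the simulated overlap cannot serve as an expected count. Each L-GMP array was assigned to the normal sort whose mean profile it correlated with best, and each normal array likewise with itself left out of its own mean. The test was also run on simulated data with 200 genes changed by a known fold: at 1.5-, 2- and 4-fold it recovered 38.8%, 85.1% and 98.5% of them in MLL-AF9 against GFP, with 9 false among 157 calls, and 59.7%, 80.6% and 100% in L-GMP against GMP, with 16 false among 176 calls. The simulated noise was independent between arrays and between genes and had no floor, so these rates need not hold for the real arrays. In the real MLL-AF9 against GFP, Meis1 (log2 change 2.82) and Sox4 (2.32) were not called without the block.

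Named genes were chosen by rule. For MLL-AF9 against GFP, L-GMP against GMP, L-GMP against HSC and HSC against GMP these are the 12 called genes with the largest change in each direction whose groups did not overlap, and for the other 6 comparisons the 3 largest. To these come up to 3 genes per direction bounded by the floor and up to 4 members of each list by p. Where fewer than 5 genes of a direction were called, the 10 of that direction with the smallest p-values are given as values only. Kit, Ly6a, Cd34, Fcgr3, Fcgr2b, Kmt2a and Mllt3 were always looked up. No probe set was assigned to Ly6a. Other genes named below were chosen after their values were seen.

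The groups, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, a floor at the 10th or 50th percentile, no floor with 16 added before log2, no filter and a stricter filter, every probe set or the mean of a gene's probe sets, a trended robust variance, array weights, a threshold of 2-fold, the 3'/5' ratio as covariate, the replicate block, only the arrays of the groups compared, and each replicate left out. For the nearest sort they were Spearman correlation, Euclidean distance, the 1000 most variable genes, and no cell cycle genes, and for the overlap of the experiments the 200 smallest p-values per direction. Those chosen after seeing the data were the omission of 3 normal arrays with low immediate early genes, the block with each pair left out, the list tests with the block, and the overlap of the experiments with response genes called under the block. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.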

Results

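Gene expression was measured in mouse haematopoietic progenitors that expressed the leukaemia fusion MLL-AF9, in the leukaemic cells that carried the surface markers of granulocyte-macrophage progenitors (GMP), and in normal stem and progenitor cells. The transduced experiment held 3 arrays of GMP expressing GFP and 3 of GMP expressing MLL-AF9. The sorted experiment held 5 arrays of a fraction enriched for haematopoietic stem cells (HSC), 4 of common myeloid progenitors (CMP), 4 of normal GMP, 3 of megakaryocyte-erythroid progenitors (MEP) and 6 of leukaemic GMP-like cells (L-GMP). Arrays of the same group correlated across genes with r from 0.944 to 0.990 in the transduced and from 0.937 to 0.984 in the sorted experiment, and genes are not independent replicates. The values are scaled array intensities on the log2 scale.

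MLL-AF9 joins parts of KMT2A (MLL), a histone methyltransferase, and MLLT3 (AF9), a subunit of a transcription elongation complex, and the transduced experiment asks which genes differ in GMP that express it. Hspa2, a member of the heat shock protein 70 family, rose 5.66-fold in MLL-AF9 against GFP (log2 change 2.50 ± 0.22 SE, adjusted p = 0.0382, 3 against 3 arrays). Pla2g7, a phospholipase secreted by macrophages, fell by 2.28 ± 0.15 on the log2 scale (adjusted p = 0.0107). Neither gene was called once any 1 of the 6 arrays was left out. Hspa2 was also not called without a filter, with every probe set or with the 3'/5' covariate, and Pla2g7 not without a filter or with a floor at the 50th percentile. Meis1, a homeobox partner of HOX proteins, stood at 9.90 ± 0.40 (SD) in MLL-AF9 and 7.09 ± 0.53 in GFP arrays, a log2 change of 2.82 ± 0.31 SE with an adjusted p of 0.104. With the replicate pair as a block its adjusted p was 0.00333.

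Of 7235 genes tested, 2 were called, 1 higher and 1 lower, and 739 had an unadjusted p under 0.05. With the replicate pair as a block, 126 genes were called, 15 higher and 111 lower. In that blocked fit Meis1 rose, and so did the HOX transcription factors Hoxa7 (log2 change 1.40, adjusted p = 0.0179) and Hoxa9 (1.56, adjusted p = 0.0362). Others that rose were Sox4, a transcription factor of progenitors (2.32, adjusted p = 0.0133), Adgrl4, an adhesion receptor (1.28, adjusted p = 0.00758), and Hoxc5 (0.94, adjusted p = 0.0248). The same held for Marcksl1 (1.22, adjusted p = 0.0253), Ajuba (1.34, adjusted p = 0.0243) and Ssbp2 (0.78, adjusted p = 0.0445). Without the block the adjusted p of these genes lay above the threshold, at 0.135 for Hoxa7, 0.382 for Hoxa9 and 0.251 for Sox4. The blocked count rested on single pairs, since it was 62, 8 and 270 without pairs 1, 2 and 3, an alternative chosen after seeing the data.

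On the lower side stood many genes of macrophages and monocytes. All 22 tested members of the monocyte and macrophage list lay below 0, with a median log2 change of -0.98, and the list was lower in MLL-AF9 (camera, adjusted p = 3.67e-15). With an estimated correlation its adjusted p = 0.548. Over all genes 0 of the 22 passed the limma test, 15 fell when adjusted over the list alone, and 12 fell over all genes in the blocked fit. Examples from the blocked fit are Mpeg1, a pore-forming protein of macrophages (-1.58, adjusted p = 0.00803), the chemokine receptors Cx3cr1 (-1.56, adjusted p = 0.0434) and Ccr2 (-0.79), and Clec7a, a receptor for fungal glucans (-0.95). Slc11a1, a metal transporter of phagosomes, and Clec4n, another receptor for fungi, also fell in the blocked fit (-1.85, adjusted p = 0.00333, and -1.96, adjusted p = 0.0123).

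The secondary granule and neutrophil list was lower in MLL-AF9 (11 genes, camera, adjusted p = 2.40e-06), and with an estimated correlation its adjusted p = 0.548. Of its members 0 passed over all genes, 2 fell when adjusted over the list alone and 4 fell in the blocked fit. Among these 4 were Mmp8, a collagenase (-1.22, adjusted p = 0.0141), Lcn2, an iron-siderophore binder (-1.53, adjusted p = 0.0147), and Pglyrp1 (-0.77, adjusted p = 0.0478). Immediate early and stress genes were lower as a list (21 genes, adjusted p = 0.000399; adjusted p = 0.662 with an estimated correlation). In that list 1 gene, Hspa1b, rose and 5 fell when adjusted over the list alone, 0 passed over all genes, and 4 fell in the blocked fit, including Atf3 (at least 5.51-fold, adjusted p = 0.00333) and Klf6 (-1.11, adjusted p = 0.0168).

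The HoxA list was higher (4 genes tested, adjusted p = 0.000120; adjusted p = 0.309 with an estimated correlation), with 0 over all genes and 3 higher both when adjusted over the list alone and in the blocked fit. Hoxa5 and Hoxa10 exceeded the median on too few arrays to be tested. Hoxa5 averaged 8.46 in MLL-AF9 and 7.31 in GFP. Hoxa10 averaged 6.93 in MLL-AF9 and was at the floor on all 3 GFP arrays. Among 11 other targets of MLL fusions, also higher as a list (adjusted p = 0.0033; adjusted p = 0.662 with an estimated correlation), 0 passed over all genes and 3 rose when adjusted over the list alone. In the blocked fit Sox4 rose and Id2, an inhibitor of helix-loop-helix factors, fell (-2.12, adjusted p = 0.0123). MYC targets and ribosome biogenesis genes were higher as a list, with 29 of 31 above 0 and a median of 0.30 (adjusted p = 2.21e-06; adjusted p = 0.662 with an estimated correlation). None of them passed the limma test, even when adjusted over the list alone. The G2 and M phase list was lower (30 genes, adjusted p = 0.00923; adjusted p = 0.663 with an estimated correlation), with 0 members called. The megakaryocyte list was lower (6 genes, adjusted p = 0.00363; adjusted p = 0.341 with an estimated correlation), with 4 genes lower when adjusted over the list alone. With the block the adjusted p of that list was 0.0588. The other 16 lists had adjusted p between 0.106 and 0.944. Kit, the stem cell factor receptor, had a log2 change of 0.80 ± 0.57 (adjusted p = 0.662, and 0.0318 with the block). The other sort markers had changes of 0.62 for Cd34 (adjusted p = 0.502), -0.23 for Fcgr3 (adjusted p = 0.497) and -0.04 for Fcgr2b (adjusted p = 0.942). Kmt2a stood at 0.17 (adjusted p = 0.818), and whether its probe set reads the fusion was not tested.

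The comparison of L-GMP with normal GMP asks how leukaemic cells differ from the progenitor whose surface markers they share. Pbx3, a homeobox cofactor of HOX proteins, rose at least 13.4-fold (log2 change 3.74 ± 0.14 SE, adjusted p = 2.28e-14, 6 against 4 arrays, 3 of the GMP arrays at the floor). Hoxa5 rose 9.30-fold (3.22 ± 0.29, adjusted p = 3.13e-08) and Meis1 rose 4.74-fold (2.24 ± 0.19, adjusted p = 7.65e-09). Prg3, a protein of eosinophil granules, rose 20.7-fold (4.37 ± 0.28, adjusted p = 1.05e-10), and Adgre1, the macrophage antigen F4/80, rose 8.69-fold (3.12 ± 0.18, adjusted p = 2.07e-11). Ccnd2, a D-type cyclin, was 16-fold lower (log2 SE 0.19, adjusted p = 1.24e-12), and Cd27, a receptor of the tumour necrosis factor family, was at least 12.6-fold lower (-3.65 ± 0.23, adjusted p = 1.29e-10, 4 L-GMP arrays at the floor). The interferon-induced membrane proteins Ifitm1 and Ifitm3 fell as well (-3.92 ± 0.21 and -3.88 ± 0.17).

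Of 8422 genes, 2825 were called, 1282 higher and 1543 lower in L-GMP, and 505 of them differed at least 2-fold. Further genes with large increases were Sgip1, an endocytic adaptor (4.14 ± 0.13), Mylk, the myosin light chain kinase (4.10 ± 0.21), Tctex1d1 (3.55), Epha7, an ephrin receptor (3.18), Aldh3b1 (3.12), the chemokine receptor Ccr1 (3.06), Baz2b (3.03) and Stfa3 (at least 7.54-fold). Further large decreases were those of Hspa1a and Hspa1b, inducible heat shock proteins (-4.38 ± 0.67 and -4.10 ± 0.52), Tmem176b (-3.99), Tgif2, a homeobox repressor (at least 14.5-fold), Rab38 (at least 12.4-fold), Phgdh, an enzyme of serine synthesis (-3.56), Serpinf1 (-3.50) and AW112010 (-3.48). Hpgd, which degrades prostaglandins, was at least 87.3-fold higher, and Igf2bp3, an RNA-binding protein of fetal tissue, at least 33.5-fold, both being at the floor on all GMP arrays. Mycn was at least 61-fold higher by the probe set that represents it, whereas another of its 3 probe sets lay at the floor on all GMP and all L-GMP arrays. Ppic, a cyclophilin, was at least 19.3-fold lower, Dmkn at least 13.6-fold and Fkbp9 at least 11.4-fold. Among 2578 genes with several kept probe sets, 21 had probe sets called in opposite directions. The number was 92 for L-GMP against HSC, 32 against CMP and 31 against MEP, with Mycn in each, and 39 for HSC against GMP. In the other comparisons it was at most 12.

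In the HoxA list 7 of 8 tested members rose over all genes and 8 when adjusted over the list alone (camera, adjusted p = 1.38e-09; adjusted p = 0.00346 with an estimated correlation). Hoxa10 was at the floor on all GMP arrays and at least 12.9-fold higher in L-GMP, and Hoxa9 rose by 2.01 ± 0.20 on the log2 scale and Hoxa7 by 0.86 ± 0.19. Among 15 other targets of MLL fusions 6 rose and 2 fell (6 and 3 when adjusted over the list alone; adjusted p = 0.0773). Those that rose included Mef2c, a transcription factor (1.52 ± 0.23), Jmjd1c, a histone demethylase (1.37 ± 0.14), Cpeb2, a translation regulator (1.68), and Lmo2, a transcription cofactor (0.77). Sox4, by contrast, fell by 0.96 ± 0.23 in L-GMP.

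**Figure D1:**
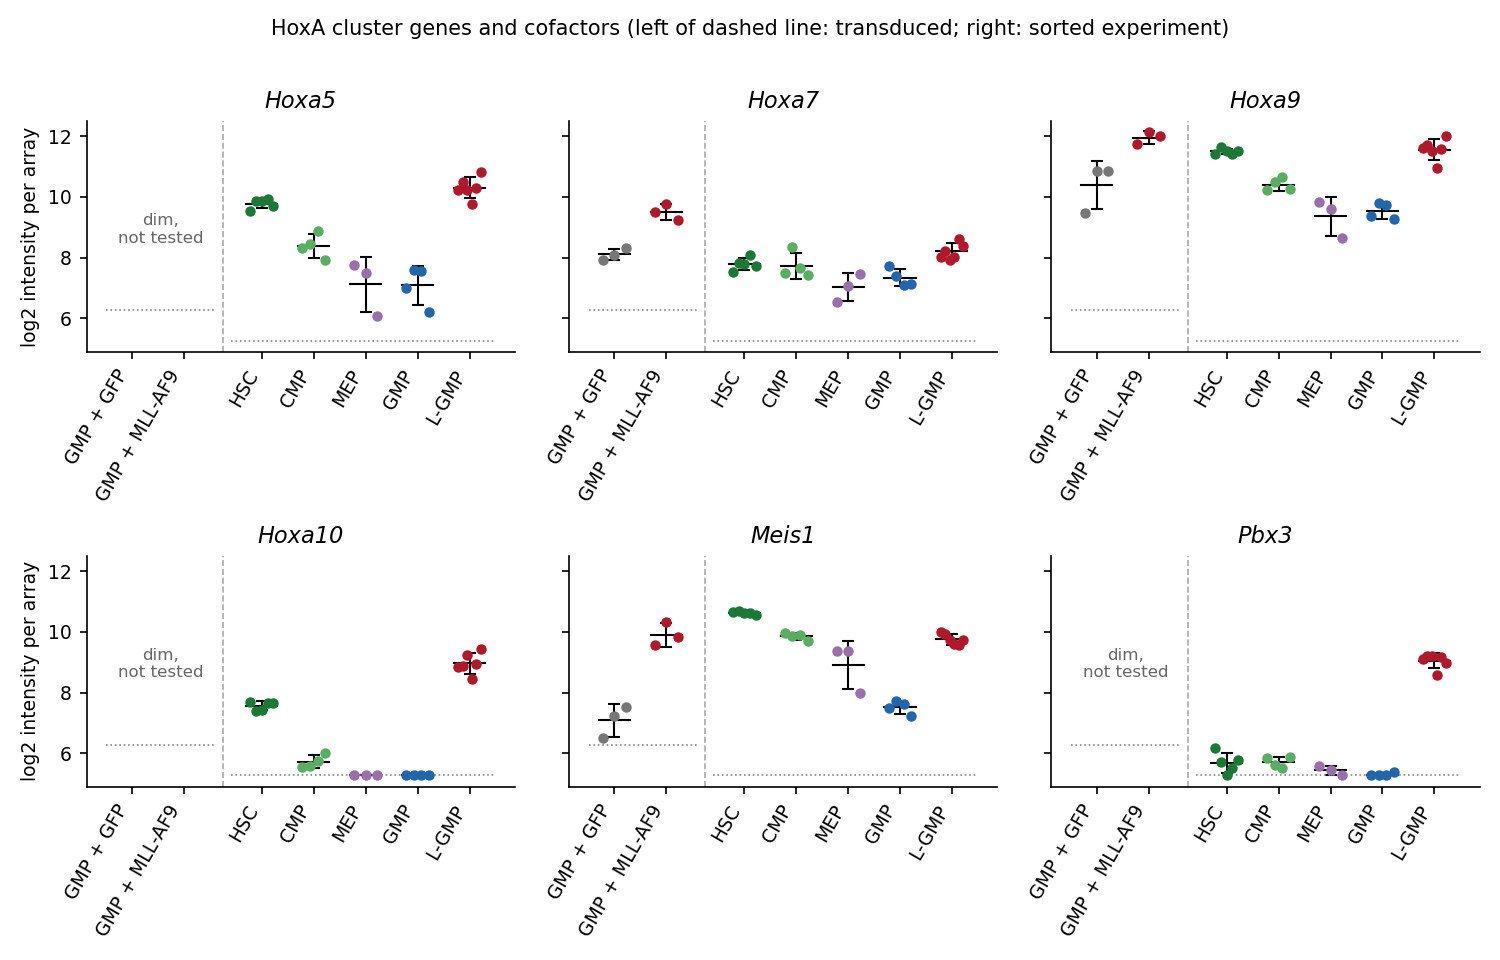
Log2 intensity of Hoxa5, Hoxa7, Hoxa9, Hoxa10, Meis1 and Pbx3 per array, with each point an array, each line a group mean, bars 1 SD, dotted lines the floor, and a dashed line between the transduced and the sorted experiments, whose levels are not comparable. Hoxa9 averaged 11.56 in L-GMP, 11.50 in HSC and 9.55 in GMP, and Hoxa10 was at the floor on every GMP and MEP array.

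Genes of myeloid maturation moved in part. Of 12 secondary granule and neutrophil genes 6 rose and 1 fell, the same counts as when adjusted over the list alone (adjusted p = 0.0171; adjusted p = 0.765 with an estimated correlation). Cd177 (at least 3.86-fold), the deiminase Padi4 (1.73) and Ltb4r1, a leukotriene receptor (1.38), were among those that rose. Of 15 primary granule genes none rose and 5 fell over all genes (1 and 5 when adjusted over the list alone; adjusted p = 0.131). Cst7, a protease inhibitor (-1.87), and Cebpa, a transcription factor of granulocytes (-1.16 ± 0.15), were among them. The monocyte and macrophage list had 7 members higher and 4 lower (7 and 5 when adjusted over the list alone; adjusted p = 0.508). Adgre1, Cd68 (1.39) and the integrin Itgam (at least 3.37-fold) were higher, and Apoe, at the floor on all L-GMP arrays, was at least 5.95-fold lower. In the mast cell, basophil and eosinophil list 3 of 8 rose and 2 fell (the same counts when adjusted over the list alone; adjusted p = 0.415). Prg3 and Gata2 (0.68) rose, and the basophil protease Mcpt8 (-1.93) and the histamine enzyme Hdc (-0.69) fell.

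The list of cyclin-dependent kinase inhibitors also held the retinoblastoma family genes Rb1, Rbl1 and Rbl2. It rose in 5 of 9 members, also when adjusted over the list alone (camera, adjusted p = 0.0123, and 0.0879 with an estimated correlation). Cdkn1c (at least 5.47-fold), Cdkn2c (1.53), Cdkn2d (1.07) and Cdkn1b (0.81), which encode proteins that restrain cell cycle entry, rose, and so did Rb1. MYC targets and ribosome biogenesis genes fell in 25 of 31 members (26 when adjusted over the list alone), with a median of -0.54 (adjusted p = 2.16e-10; adjusted p = 0.0703 with an estimated correlation). Myc itself fell (-0.97 ± 0.10), as did Srm, an enzyme of spermidine synthesis (-1.04). None of 29 S phase genes rose and 5 fell (3 when adjusted over the list alone; adjusted p = 0.193), and 1 of 30 G2 and M phase genes rose (0 when adjusted over the list alone; adjusted p = 0.665). In the WNT list 1 of 14 rose and 5 fell (1 and 6 when adjusted over the list alone; adjusted p = 0.193). Ccnd2, Ccnd1 (at least 4.22-fold) and the effector Ctnnb1 (-0.32) fell while Ccnd3 rose (1.18).

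Interferon-stimulated genes fell in 10 of 22 members, also when adjusted over the list alone (adjusted p = 0.0123; adjusted p = 0.409 with an estimated correlation). Examples are Rtp4 (at least 3.77-fold), the GTPases Gbp2 (-1.29) and Ifi47 (-0.92), and Bst2, which tethers viruses (-0.99). Of 29 immediate early and stress genes 5 fell, also when adjusted over the list alone (adjusted p = 0.0123; adjusted p = 0.878 with an estimated correlation). They were Hspa1a, Hspa1b, Klf4, a transcription factor (-2.88), Myc and Ppp1r15a. The mean level of that list lay between 6.99 and 7.64 on the L-GMP arrays, at 7.25 on replicate 1 of GMP and between 8.63 and 9.04 on the other GMP arrays. It was also low on replicate 1 of CMP and of HSC. Without these 3 normal arrays 19 of the 29 fell in L-GMP (adjusted p = 1.66e-08; adjusted p = 0.182 with an estimated correlation). The arrays were left out because of these same genes, after seeing the data, so the larger count follows in part from that choice.

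**Figure D2:**
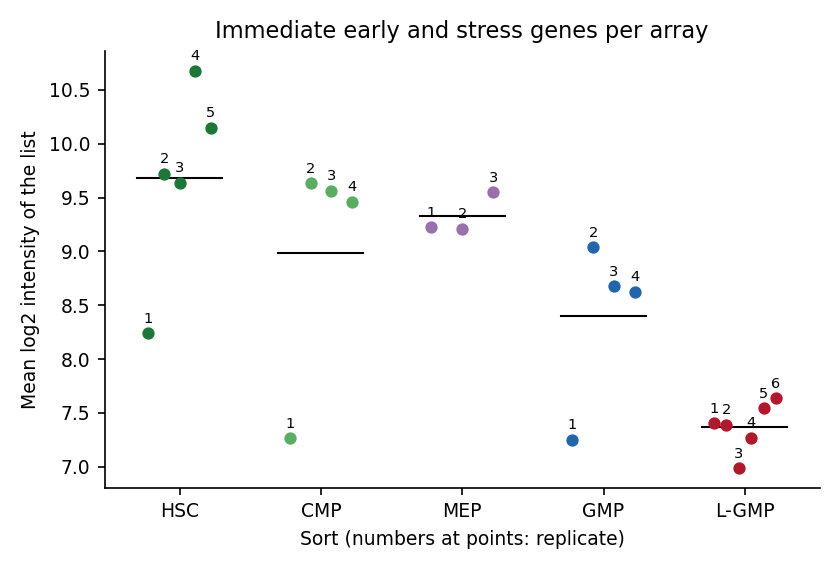
Mean log2 intensity of the immediate early and stress list on each of the 22 arrays of the sorted experiment, by sort, with replicate numbers beside the points. L-GMP arrays lay between 6.99 and 7.64, and replicate 1 of CMP and of GMP lay within that range.

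The stem cell list of 29 genes went both ways, with 5 higher and 7 lower, also when adjusted over the list alone (adjusted p = 0.685). Ifitm1, Ifitm3 and Tal1, a transcription factor (at least 4.55-fold), fell, while Mycn, read by the probe set described above, and Cdkn1c rose. Lymphoid priming genes (2 of 15 higher, 1 lower; adjusted p = 0.705), erythroid genes (5 of 28 higher, 5 lower; adjusted p = 0.84) and megakaryocyte genes (2 of 11 higher, 3 lower; adjusted p = 0.685) had the same counts when adjusted over the list alone. The thrombin receptor F2r was at least 5.73-fold lower, and Selp, an adhesion molecule of platelets, fell at least 2.89-fold. Counts were also the same over the list alone for T and NK cell genes (2 of 8 lower, Cd27 and Gzmb; adjusted p = 0.665), B cell genes (1 of 6 higher; adjusted p = 0.852) and dendritic cell and MHC class II genes (3 of 9 higher, 3 lower; adjusted p = 0.765). Of the last group the transcription factor Tcf4 rose (1.27) and the class II gene H2-Aa fell at least 4.84-fold. The same held for stroma and endothelium (1 of 8 higher; adjusted p = 0.687), glycolysis (1 of 15 higher, 5 lower; adjusted p = 0.301), ribosomal proteins (1 of 33 lower, Rpl14 at -1.18; adjusted p = 0.357) and sort markers (1 of 4 higher, 2 lower; adjusted p = 0.747). Median and test differed in sign for T and NK cell genes (median 0.23, mean -0.52, test lower) and for B cell genes (median -0.08, mean -0.01, test higher). Among the sort markers Kit fell by 0.49 ± 0.13, Cd34 fell by 0.87 ± 0.24 and the Fc receptor Fcgr2b rose by 0.62, while Fcgr3 stood at 0.14 (adjusted p = 0.513). Kmt2a fell by 0.60 (adjusted p = 0.0156) and Mllt3, with an adjusted p of 0.714, was at the floor on most arrays of both groups. Xist, the sole sex-linked gene tested, stood at 0.24 (adjusted p = 0.134).

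**Figure D3:**
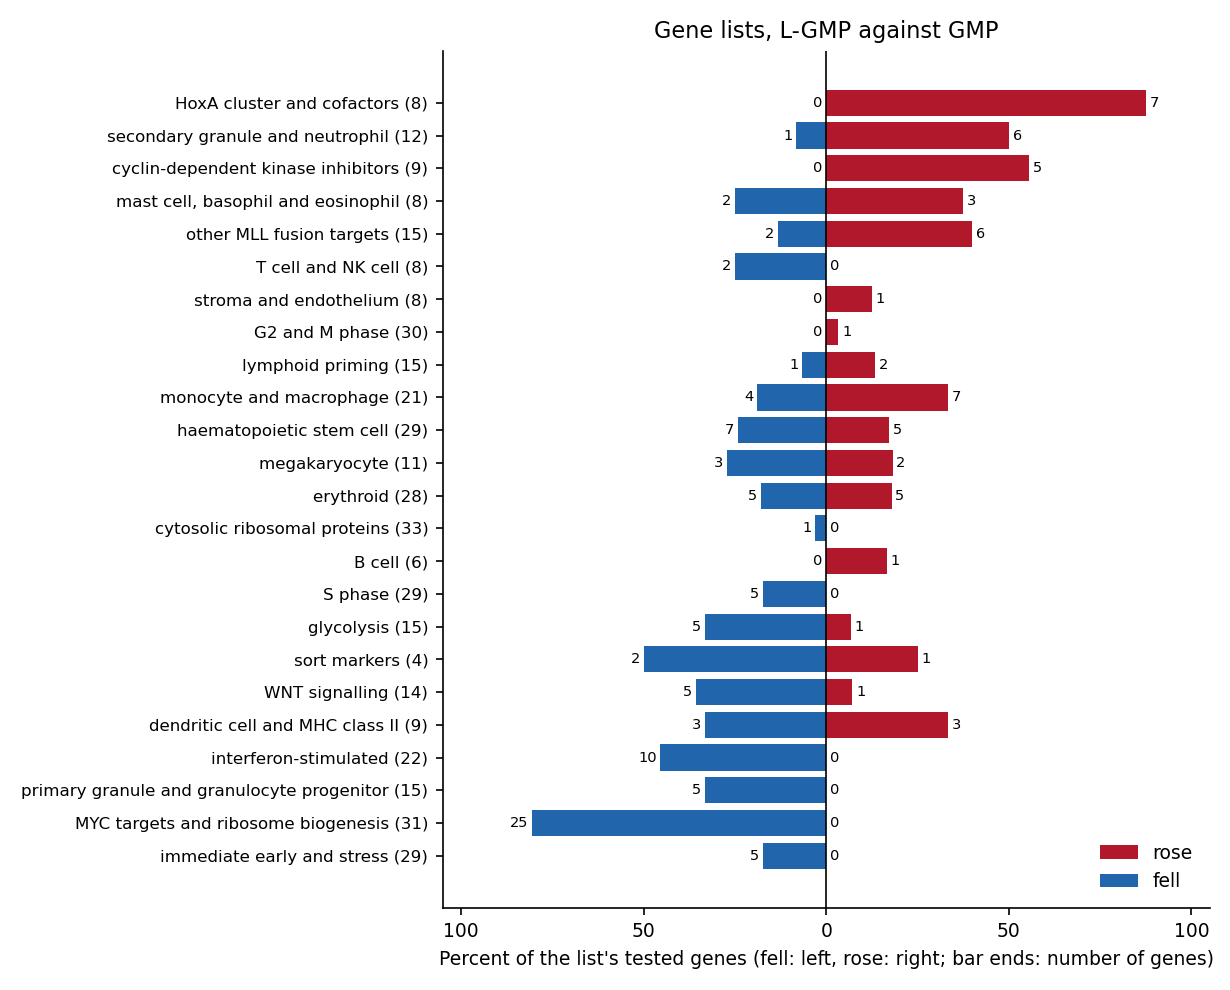
Percent of the tested genes of each list that rose (red, to the right) or fell (blue, to the left) in L-GMP against GMP, with the number of genes at each bar and the size of the list in parentheses. In the HoxA list 7 of 8 genes rose and in the MYC target list 25 of 31 fell.

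Against HSC, the comparison asks how far leukaemic cells are from the stem cell fraction. Haptoglobin, Hp, rose 45.6-fold (log2 change 5.51 ± 0.45 SE, adjusted p = 1.61e-09, 6 against 5 arrays) and neutrophil elastase, Elane, 38.9-fold (5.28 ± 0.50). Igsf6 rose 38.0-fold (5.25 ± 0.35), Ly86 33.0-fold (5.04 ± 0.19) and Adgre1 at least 32.3-fold (5.01 ± 0.17, 3 HSC arrays at the floor). Genes that fell were Ifitm1 (-6.02 ± 0.19), Hlf, a transcription factor of stem cells (-5.44 ± 0.19, adjusted p = 1.20e-15), Rgs1, a regulator of G protein signalling (at least 56.3-fold), and the interferon-stimulated Rtp4 (at least 40.6-fold). Dntt, the terminal transferase of lymphoid cells, was at least 61.4-fold lower, F2r at least 53.5-fold and Ctla2a at least 116-fold. Procr, a marker of stem cells, was at least 15.3-fold lower.

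In all, 3976 genes were called, 1968 higher and 2008 lower in L-GMP. Stem cell genes fell in 19 of 29 members and rose in 2 (20 and 2 when adjusted over the list alone; camera, adjusted p = 7.59e-09; adjusted p = 0.0253 with an estimated correlation). Among those that rose was Mycn, by the probe set described above. Another Mycn probe set went the other way, with a scaled intensity of 457 ± 70.0 (SD) in HSC and the floor on all 6 L-GMP arrays. Interferon-stimulated genes fell in 17 of 22, also when adjusted over the list alone (adjusted p = 3.47e-09; adjusted p = 0.0270 with an estimated correlation). Lymphoid priming genes fell in 9 of 15 and rose in 1 (10 and 1 when adjusted over the list alone; adjusted p = 0.00726; adjusted p = 0.0386 with an estimated correlation). Mast cell, basophil and eosinophil genes rose in 5 of 8 and fell in 1, also when adjusted over the list alone (adjusted p = 0.00991; adjusted p = 0.0495 with an estimated correlation). Without replicate 1 of HSC, CMP and GMP, the 3 arrays low for immediate early genes, the adjusted p with an estimated correlation was 0.0549 for the stem cell, interferon and lymphoid lists and 0.0912 for the mast cell list, so all 4 lay above the threshold. Prg3 was at least 32.5-fold and Hdc at least 20.9-fold higher. Primary granule genes rose in 14 of 15 and fell in 1 (adjusted p = 2.41e-06; adjusted p = 0.110 with an estimated correlation). Monocyte genes rose in 14 of 21 and fell in 4 (adjusted p = 4.35e-05; adjusted p = 0.126 with an estimated correlation). Of 12 secondary granule genes 6 rose and 1 fell (6 and 2 when adjusted over the list alone; adjusted p = 0.0797; adjusted p = 0.635 with an estimated correlation). G2 and M phase genes rose in 27 of 30, such as Aurka (1.43) and Birc5 (0.87) (adjusted p = 2.86e-06; adjusted p = 0.393 with an estimated correlation). Adjusted over the list alone, 14 primary granule genes, 15 monocyte genes and 29 G2 and M phase genes rose, and 1, 4 and 1 fell. Immediate early and stress genes fell in 24 of 29, also when adjusted over the list alone (adjusted p = 1.38e-05; adjusted p = 0.393 with an estimated correlation). Their list mean was 8.24 on replicate 1 of HSC and 9.64 to 10.68 on the other HSC arrays.

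Within the HoxA list Hoxa9 (0.06 ± 0.19, adjusted p = 0.827) and Hoxa5 (0.52 ± 0.28, adjusted p = 0.130) did not pass the test between L-GMP and HSC. Pbx3 (3.35 ± 0.14) and Hoxa10 (1.40 ± 0.13) rose and Meis1 fell by 0.87 ± 0.18 in L-GMP. In all, 2 of 8 members rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.0791). Fcgr3 was at least 20.8-fold higher and Fcgr2b rose by 3.34, while Kit (-1.46) and Cd34 (-1.70) fell. The mouse genes of the fusion partners, Kmt2a (-1.72) and Mllt3 (at least 2.82-fold), fell too.

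Against CMP, 3357 genes were called (1546 higher and 1811 lower in L-GMP, 6 against 4 arrays). The monocyte lectin Clec4a2 rose 28.7-fold (log2 change 4.84 ± 0.32), Adgre1 28.4-fold (4.83 ± 0.18) and Gpc1, a glypican, by 4.61 ± 0.09. Platelet factor 4, Pf4, fell by 4.94 ± 0.47 (adjusted p = 2.93e-08), and F2r was at least 94.2-fold lower. Megakaryocyte genes fell in 9 of 11 (adjusted p = 0.0002; adjusted p = 0.103 with an estimated correlation), with 9 lower and 2 higher when adjusted over the list alone. The HoxA list rose in 5 of 8, and in 6 when adjusted over the list alone (adjusted p = 0.000403; adjusted p = 0.103 with an estimated correlation). Fcgr3 was higher by 4.18 and Fcgr2b by 2.20, and Kit (-1.11) and Cd34 (-1.49) fell.

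Against MEP, 3803 genes were called (1876 higher and 1927 lower in L-GMP, 6 against 3 arrays). Car1, a carbonic anhydrase of red cells (-6.32 ± 0.42, adjusted p = 5.23e-11), and Aqp1, a water channel of red cells (at least 50.5-fold), fell. Hp rose 50.7-fold (5.66 ± 0.53) and Anxa3, an annexin of neutrophils, 41.0-fold (5.36 ± 0.32). Erythroid genes fell in 21 of 28 and rose in 2, also when adjusted over the list alone (adjusted p = 3.92e-10; adjusted p = 0.0228 with an estimated correlation). The HoxA list rose in 7 of 8, also when adjusted over the list alone (adjusted p = 1.76e-05; adjusted p = 0.0333 with an estimated correlation). Without the 3 low arrays both lists had an adjusted p of 0.0629 with an estimated correlation. All 15 primary granule genes rose (adjusted p = 5.15e-09; adjusted p = 0.0615 with an estimated correlation). Cd34 rose by 1.80 and Fcgr3 was at least 20.8-fold higher, while Kit fell by 1.29.

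To ask which normal sort the leukaemic cells resembled most, each L-GMP array was correlated with the mean profile of each normal sort across 8422 genes. All 6 L-GMP arrays were nearest to GMP, with a mean r of 0.912 ± 0.0073 (SD, n = 6), ahead of CMP (0.856 ± 0.00685), HSC (0.809 ± 0.00673) and MEP (0.797 ± 0.00732). All 16 normal arrays were nearest to their own sort. Nearest did not mean close: single L-GMP arrays correlated with the GMP mean at 0.904 to 0.924. Normal GMP arrays, each left out of the mean, did so at 0.960 to 0.985, and normal CMP arrays at 0.938 to 0.941. These correlations are across genes, which are not independent replicates.

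**Figure D4:**
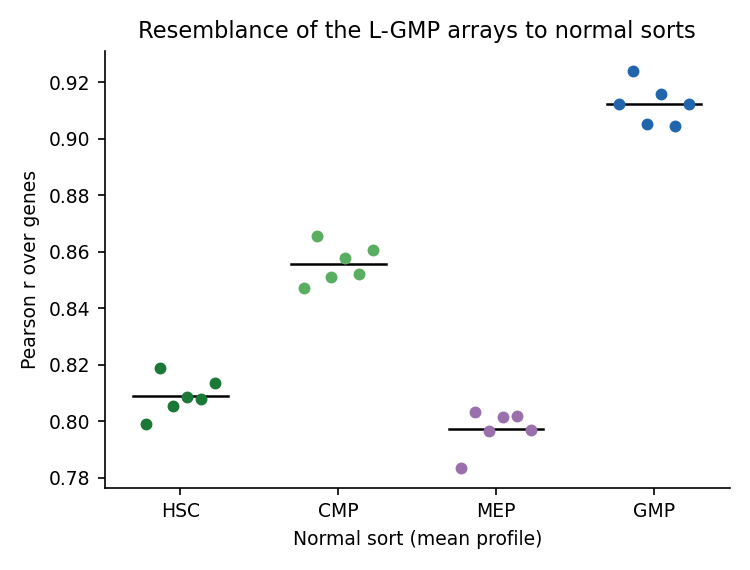
Pearson correlation across genes of each of the 6 L-GMP arrays with the mean profile of HSC, CMP, MEP and GMP, each point an array and each line the mean of 6. The mean was 0.912 with GMP and 0.856 with CMP, the next nearest sort.

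The study's title asks whether a stem cell program is active in the leukaemic cells. In these arrays 386 genes were higher in HSC than in each of GMP, CMP and MEP, and 93 of them were higher in L-GMP than in GMP, where 58.8 would come from the list sizes alone. Among the 93 were Mylk, Hoxa10, Hoxa5, Hoxa9, Meis1, Cdkn1c and Lmo2, with the values given above. Others were Hoxa3, Ebi3, a cytokine subunit (1.88 ± 0.20), Lst1 (2.47 ± 0.17) and Ets1, a transcription factor (0.98 ± 0.27). In the other direction, 80 program genes were lower in L-GMP, where 70.7 would come from the list sizes, and 213 were not called. Those that fell included Ifitm3, Rab38 and AW112010, as above, Hlf (-1.80 ± 0.20) and Basp1 (-2.48). Of the 93 genes, 27 exceeded their HSC level in L-GMP. Higher in L-GMP than in GMP, CMP and MEP alike were 45 of the 386 program genes, against 773 of all 8422 genes tested.

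Put as shares, 24.1% of the program and 15.2% of all genes were higher in L-GMP, and 20.7% and 18.3% were lower. The median log2 change of the program, L-GMP against GMP, was 0. The list was chosen on these same HSC and GMP arrays, so its count is not independent evidence of its direction. When different GMP arrays defined the list and the comparison, between 63 and 77 program genes were higher, between 1.58 and 2.03 times the expected number over 6 splits, and between 50 and 77 were lower, between 1.08 and 1.55 times the expected number. A list defined without GMP held 428 genes, of which 110 were higher (65.2 expected) and 88 lower (78.4 expected), and its median log2 change was also 0. Genes at the floor on all GMP arrays, such as Hoxa10 and Hoxa3, could be called only higher in L-GMP. The expected numbers were not matched for level, so neither the splits nor this list removes that limit. Over all genes the changes HSC against GMP and L-GMP against GMP correlated with r = 0.0205, whereas 100 simulated data sets in which L-GMP did not differ from GMP gave 0.148 on average from the shared arrays. In the simulation the L-GMP change was noise only, so these 2 correlations are not on the same scale. The covariance was 0.00832 in the data and 0.0189 on average in the simulation (0.0142 to 0.0237). With different GMP arrays in the 2 contrasts r lay between -0.0992 and 0.0548.

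In the transduced experiment 234 of the program genes were tested, and as a list they were lower in MLL-AF9 than in GFP (camera p = 5.31e-08; p = 0.0165 with an estimated correlation), with a median log2 change of -0.16 and 73 genes above 0. With the replicate pair as a block the list p was 9.64e-08, and 0.07 with an estimated correlation. None of the 234 passed the limma test over all genes without the block, 1, Meis1, rose when adjusted over the list alone, and 3 rose and 12 fell in the blocked fit. The 67 tested genes that were shared between HSC and L-GMP were lower as well (camera p = 1.31e-08, and 0.0689 with an estimated correlation, or 0.127 with the block too). For the program, arbitrary regroupings of these arrays gave a median camera p of 0.0117 at the preset correlation. The small p-values at that correlation are therefore weak evidence of a fall.

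The changes of the transduced and the sorted experiment were set side by side for the 6865 genes tested in both. Under the fit without a block, 0 of the MLL-AF9 response genes in this set were called in L-GMP against GMP (limma), where 0.156 would be expected among 1 higher gene. Among genes called with the block, Meis1, Hoxa9, Hoxa7, Hoxc5 and Gata2 were higher in both comparisons, 5 genes where 2.19 would be expected from 14 higher genes. Another 16 genes, such as Klf4, Ccr2 and the calcium-binding S100a4, were lower in both, where 20.5 would be expected from 98. A further 49 genes were called in opposite directions. Sox4, Kit, Cttn and Phtf2 were higher in MLL-AF9 and lower in L-GMP, 4 genes where 2.93 would be expected. The other 45, such as Adgre1, Cd68, Clec4a2, Id2, Slc11a1 and Pglyrp1, were lower in MLL-AF9 and higher in L-GMP, where 15.3 would be expected. That selection was chosen after seeing the data. Across the 6865 genes the changes correlated with Pearson r = -0.296 and Spearman rho = -0.338, and genes are not independent replicates. The 2 changes have different controls, and the difference between them was not tested.

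**Figure D5:**
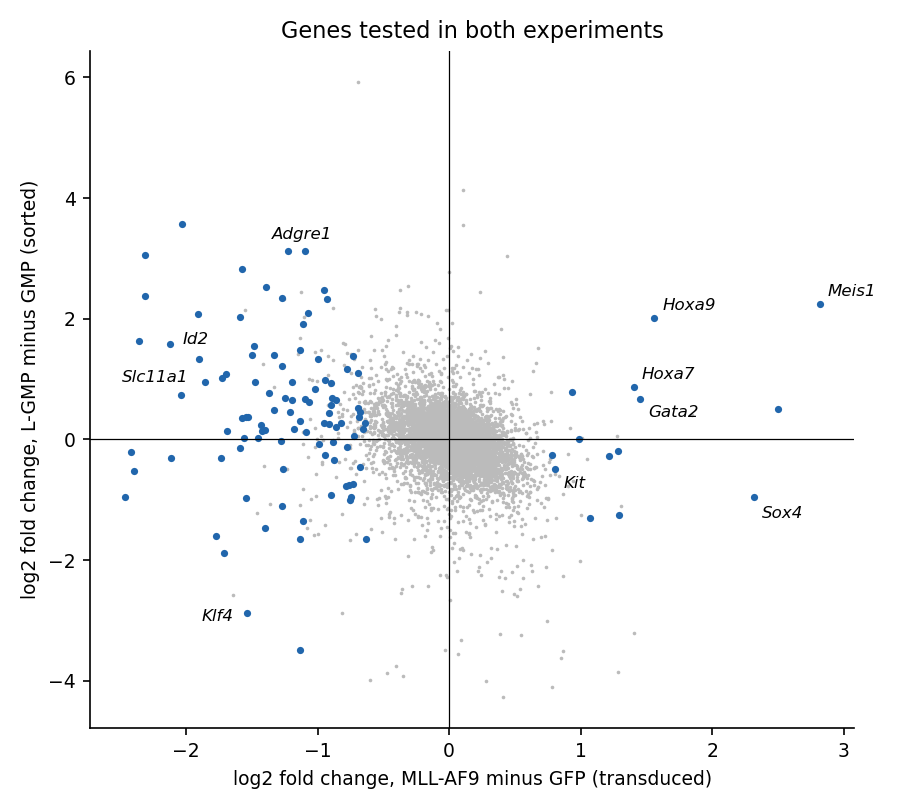
Log2 change MLL-AF9 minus GFP (x) against log2 change L-GMP minus GMP (y) for the 6865 genes tested in both experiments, in grey, with genes called under the replicate block in MLL-AF9 against GFP in blue and 10 genes labelled. Meis1, Hoxa9 and Hoxa7 lie to the upper right, Sox4 and Kit to the lower right and Adgre1 and Id2 to the upper left.

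Among normal sorts, HSC against GMP compares the fraction enriched for stem cells with a myeloid progenitor. Dntt rose at least 53.6-fold in HSC (log2 change 5.74 ± 0.24 SE, adjusted p = 1.24e-13, 5 against 4 arrays, 3 of the GMP arrays at the floor), Vldlr, a lipoprotein receptor, 22.4-fold (4.48 ± 0.24), Flt3, a cytokine receptor of early progenitors, 13.4-fold (3.75 ± 0.30) and Hlf 12.5-fold (3.64 ± 0.21). Elane (-5.53 ± 0.55), Ms4a3, a marker of granulocyte-monocyte progenitors (-5.13 ± 0.46), Igsf6 (-4.90 ± 0.39) and Ctsg, a granule protease (-3.96 ± 0.34), fell. The cytokine Ltb was at least 27.2-fold higher and Tgm2, a transglutaminase, at least 24.7-fold, and Hdc was at least 33.7-fold and Fcgr3 at least 18.8-fold lower. Of 3469 called genes 1636 were higher and 1833 lower in HSC.

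Stem cell genes rose in 20 of 29 members in HSC against GMP (22 when adjusted over the list alone; adjusted p = 7.16e-13; adjusted p = 0.00363 with an estimated correlation). Lymphoid priming genes rose in 9 of 15, also when adjusted over the list alone (adjusted p = 0.000557; adjusted p = 0.0121 with an estimated correlation), as did the HoxA list in 6 of 8, or 7 when adjusted over the list alone (adjusted p = 4.17e-05; adjusted p = 0.0319 with an estimated correlation). Meis1 rose by 3.11 ± 0.19, Hoxa9 by 1.95 ± 0.21 and Hoxa5 by 2.69 ± 0.31, and Hoxa10 was at least 4.89-fold higher. Interferon-stimulated genes rose in 14 of 22 and fell in 1 (15 and 1 when adjusted over the list alone; adjusted p = 2.81e-07; adjusted p = 0.0326 with an estimated correlation), and Irf7, a regulator of interferon genes, rose by 1.98. Primary granule genes fell in 12 of 15 (13 when adjusted over the list alone; adjusted p = 7.26e-10; adjusted p = 0.0326 with an estimated correlation). S phase genes fell in 16 of 29 (17 when adjusted over the list alone; adjusted p = 0.000476; adjusted p = 0.397 with an estimated correlation). G2 and M phase genes fell in 21 of 30 (25 lower and 1 higher when adjusted over the list alone; adjusted p = 5.26e-06; adjusted p = 0.397 with an estimated correlation). Immediate early and stress genes rose in 12 of 29 and fell in 1 (14 and 1 when adjusted over the list alone; adjusted p = 0.00973; adjusted p = 0.562 with an estimated correlation). Replicate 1 of both sorts was low for them. Without the 3 low arrays the adjusted p with an estimated correlation was 0.0634 for the HoxA, 0.0711 for the primary granule and 0.0849 for the interferon list. Kit rose by 0.97, Cd34 by 0.84, Kmt2a by 1.11 and Mllt3 at least 2.96-fold, and Fcgr2b fell by 2.72. Secondary granule genes had a median of 0.32 and a mean of 0.11 while the test pointed lower (adjusted p = 0.8).

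Between HSC and CMP 1132 genes were called, 506 higher and 626 lower in HSC (5 against 4 arrays), and without replicate 4 of CMP the count was 689. Procr rose 13-fold (3.70 ± 0.10, adjusted p = 5.63e-16), the GTPase Gbp6 12.4-fold (3.63 ± 0.16) and Ltb 9.86-fold (3.30 ± 0.23), while Cpa3, a carboxypeptidase of mast cells (-3.85 ± 0.38), and Ly86 (-3.40 ± 0.21) fell. Interferon-stimulated genes rose in 12 of 22 (13 when adjusted over the list alone; adjusted p = 1.15e-08; adjusted p = 0.0183 with an estimated correlation). Stem cell genes rose in 13 of 29 (14 higher and 2 lower when adjusted over the list alone; adjusted p = 1.59e-08; adjusted p = 0.0183 with an estimated correlation). Without the 3 low arrays the adjusted p with an estimated correlation was 0.0551 for both, and 8 interferon and 11 stem cell genes rose. Between HSC and MEP 2772 genes were called, 1464 higher and 1308 lower in HSC (5 against 3 arrays). Car1 fell by 6.48 ± 0.43 and Klf1, the erythroid transcription factor, was at least 36.4-fold lower, while Dntt rose 23.4-fold (4.55 ± 0.26) and Cd34 rose by 3.50. Erythroid genes fell in 19 of 28 and rose in 2 (20 and 2 when adjusted over the list alone; adjusted p = 5.08e-14; adjusted p = 0.00495 with an estimated correlation).

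Between CMP and GMP 1413 genes were called, 724 higher and 689 lower in CMP (4 against 4 arrays). Dntt rose at least 31.3-fold (4.97 ± 0.26, 3 GMP arrays at the floor), F2r 16.4-fold (4.04 ± 0.14) and Pf4 by 3.51 ± 0.52, while the steroid enzyme Hsd11b1 (-4.38 ± 0.46), Fcgr3 (-4.04 ± 0.16) and Elane (-4.04 ± 0.58) fell. Megakaryocyte genes rose in 8 of 11 (9 when adjusted over the list alone; adjusted p = 2.52e-09; adjusted p = 0.00607 with an estimated correlation). Erythroid genes rose in 12 of 28 (13 when adjusted over the list alone; adjusted p = 4.61e-08; adjusted p = 0.0157 with an estimated correlation). Between MEP and GMP 2314 genes were called, 999 higher and 1315 lower in MEP (3 against 4 arrays). Car1 rose 82.7-fold (6.37 ± 0.45) and Aqp1 at least 48.9-fold, Gfi1b, a repressor of red cells and platelets, was at least 22.2-fold higher, and Igsf6 fell at least 36.1-fold. Erythroid genes rose in 23 of 28 and fell in 1 (23 and 2 when adjusted over the list alone; adjusted p = 3.78e-18; adjusted p = 0.00125 with an estimated correlation). Primary granule genes fell in 14 of 15 (15 when adjusted over the list alone; adjusted p = 5.09e-16; adjusted p = 0.0121 with an estimated correlation).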

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

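The tests of explanations in this part were chosen after the results were seen, except the list test in MLL-AF9 against GFP and the split of the GMP arrays, which were planned. A sample was singled out when its gap to the nearest array of its group, as a share of the range of the group, exceeded Dixon's 95% critical value. Chance alone gives that in about 1 in 20 groups, and here it was met in 27 of 333 tests (8.11%): 8 of 100 list means, 1 of 20 array measures and 18 of 213 genes. Shares are given in parentheses and levels are log2 intensities.

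Immediate early and stress genes were low on the L-GMP arrays, with list means between 6.99 and 7.64, and on replicate 1 of CMP, where the mean was 7.27 against 9.46 to 9.63 on the other CMP arrays (0.928). These genes respond within minutes to handling, and 2 of the 16 normal arrays, replicate 1 of CMP and of GMP, lay at or below the highest L-GMP array. That observation raised the question of differences in handling or sorting between arrays and so cannot decide it. Lower immediate early transcription in leukaemic cells could be looked for only in MLL-AF9 against GFP, where the list was lower at the preset correlation (camera, adjusted p = 0.000399), 4 of its 21 genes fell in the blocked fit, and its adjusted p with an estimated correlation was 0.662. Both explanations therefore cannot be told apart with these arrays, since no sort holds enough arrays of both kinds.

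Mycn was high in L-GMP by 1 of its 3 probe sets, with a scaled intensity of 2598 ± 1190 (SD, n = 6) against values at or below 0 on all 16 normal arrays. A rise of the Mycn transcript that all its probe sets read is argued against, because a second probe set, which read 457 ± 70.0 in HSC, was above the floor on 0 of the 6 L-GMP arrays. The first probe set was also high in the transduced GMP, at 6872 ± 1480 with GFP and 4303 ± 1190 with MLL-AF9 (SD, n = 3 each). On 28 of 28 arrays the signal was low in normal cells and high in transduced or leukaemic ones, and a candidate explanation is sequence of the retroviral vector. The sequence of the vector is not given in the sources used here, so that explanation stays a hypothesis.

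Stem cell program genes were higher in L-GMP than in GMP in 93 cases. Stem cells left in the L-GMP sort are argued against, since the titles give a Sca-positive sort for HSC and a Sca-negative one for L-GMP, and since RNA of HSC would bring the genes most specific to HSC along. The 20 program genes with the largest ratio of HSC to GMP stood in L-GMP at 1.62% to 17.1% of their HSC level (median 5.96%, upper quartile 7.6%). Each such level is an upper limit on the share of HSC RNA. The 93 genes would need shares of at least 8.18% (lower quartile 36.9%), and 88 of them more than 17.1%. The other 5 would still need more than the upper quartile of these levels, provided that cells left over had the mean profile of HSC. The GMP arrays that both contrasts share are argued against as the source of the higher count, with a lowest ratio of observed to expected genes of 1.58 when different GMP arrays were used, though lower genes were also above the expected number there (1.08 to 1.55). Expression of part of the program by the leukaemic cells may remain, as a hypothesis found and tested on the same arrays.

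On replicate 3 of HSC the monocyte and macrophage list averaged 8.10 against 7.38 to 7.49 on the others (0.843) and the erythroid list 7.11 against 7.18 to 7.21 (0.728). On the same array Bex1 was low at 10.09 (0.760) and Tgm2 low at 9.41 (0.770), and Slpi was high at 8.09 against 7.56 to 7.66 (0.821). Replicate 4 of HSC was low for the S phase list, at 8.97 (0.741), for Iigp1, at 10.25 (0.739), and for Myl10, at 9.09 against 10.35 to 10.72 (0.771).

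On replicate 1 of CMP the B cell list was high at 7.83 against 7.64 to 7.66 (0.932) and Rgs1 low at 8.12 against 10.72 to 10.98 (0.908). Adgre1 was high on replicate 3 of CMP, at 6.16 (0.842). Replicate 4 of CMP was the lowest for Baz2b (0.855), Hdc (0.861), Ifitm1 (0.919), Ifitm3 (0.919), Papss2 (0.957) and Tmem176b (0.852) and for the sex-linked list, at 12.02 against 12.42 to 12.47 (0.895).

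On replicate 4 of GMP the stem cell list was low at 6.85 against 7.01 to 7.04 (0.861), AW112010 was low (0.850) and Rtp4 was low (0.830), while Clec4a2 was high at 9.26 against 8.12 to 8.23 (0.904) and Hsd11b1 high at 10.81 (0.852). Replicate 1 of GMP had a high erythroid list, at 6.98 against 6.90 to 6.91 (0.924), and the highest scale factor of its group, 1.04 against 0.976 to 0.985 (0.867). In L-GMP, Pbx3 was low on replicate 4, at 8.58 against 8.99 to 9.22 (0.643).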

How the results depend on the processing

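The alternatives that left out pairs from the block or 3 normal arrays, the list tests with the block or without these arrays, and the overlap with response genes called under the block were chosen after seeing the data, and the others were planned. Counts of called genes stayed within 1.5 times the reported value, and tests of named genes and of the program on their side of the threshold, except as given here, and the cause was not tested unless stated. The count for MLL-AF9 against GFP, 2, became 1 without a filter, with every probe set and with the 3'/5' covariate, 83 with array weights and 126 with the replicate block, or 62, 8 and 270 with the block and pair 1, 2 or 3 left out. Array weights gave 1945 for HSC against CMP, 2332 for CMP against GMP, 165 program genes and 23 genes shared by both experiments. That overlap, 0, became 1 with a trended robust variance, 20 with the block in both experiments, 21 with the block in the transduced one and 54 with the 200 smallest p per direction (19 higher in both where 31.3 would be expected, 35 lower in both where 41.8 would be expected, 93 higher then lower where 41.8 would be expected, and 73 lower then higher where 31.3 would be expected).

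A threshold of 2-fold lowers a count by construction, to 505, 1163, 888 and 1282 for L-GMP against GMP, HSC, CMP and MEP, 834, 209 and 761 for HSC against GMP, CMP and MEP, 355 and 780 for CMP and MEP against GMP, and 14 program genes. With that threshold the camera p of the program in the transduced experiment was 0.149 (28 genes). With each array left out it ranged from 3.83e-09 to 2.21e-06.

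With each replicate left out in turn the counts were 0 to 0 for MLL-AF9 against GFP, 2315 to 2738 for L-GMP against GMP, 3662 to 3903 against HSC, 2977 to 3316 against CMP, 3368 to 3776 against MEP, 3000 to 3555 for HSC against GMP, 689 (without replicate 4 of CMP) to 1213 for HSC against CMP, 1964 to 2711 for HSC against MEP, 1074 to 1354 for CMP against GMP, 1839 to 2167 for MEP against GMP, 73 to 102 for the program and 0 to 1 for the overlap. Every L-GMP array was nearest to GMP under each alternative run. Without the 3 normal arrays, of 216 list tests in the sorted experiment, 5 of 109 passed no longer and 10 came to pass with the preset correlation, and 18 of 32 passed no longer and 0 came to pass with an estimated one; those of lists named as called in the report are given there.

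Without a floor the log2 change turned to -0.41 for Mycn, L-GMP against GMP, -4.65 for Mycn, L-GMP against HSC, -3.38 for Mycn, L-GMP against CMP, and -3.35 for Mycn, L-GMP against MEP. Both L-GMP and GMP lay at background by the probe set read there, so the first of these shows no change of direction. With a floor at the 10th percentile the values against HSC, CMP and MEP were -4.84, -3.50 and -3.45. Other sign changes were Col5a1 in HSC against MEP without a filter (0.66), Rpl22 in HSC against GMP with every probe set (1.30) or their mean (0.55), Rpl22 in HSC against MEP (0.078) and Rpl41 in HSC against GMP (0.028) with the mean. In each of these cases other probe sets of the gene were read. Of 825 calls of named genes, followed over 19803 runs, 19362 kept direction and call, 429 lost the call and 12 changed sign. Of 246 results not called, 251 of 5281 runs passed the threshold. Probe sets near the floor limit what can be seen: values below it have no order, and a bound stands in place of a fold.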

Other observations

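The scan of probe sets and the splits of the arrays in this part were chosen after the results were seen. Of 22626 probe sets, 9 were at the floor on all 16 normal arrays of the sorted experiment and above the median on all 6 L-GMP arrays. Besides those of Hpgd, Igf2bp3 and Mycn they read Penk, the precursor of enkephalins (scaled intensity 1360 ± 608 SD, n = 6), Dsp, a protein of desmosomes (482 ± 77.8), Apoc2, an apolipoprotein (472 ± 125), Ccdc80 (305 ± 92.4) and Col19a1, a collagen (202 ± 56.0). In the transduced experiment Penk read 79.3 to 166, Dsp 37.0 to 64.2 and Igf2bp3 82.1 to 192, below the median of that experiment on every array, whereas Apoc2 read 111 to 2214 and exceeded the median on 4 of 6 arrays. These genes were chosen after their values were seen.

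The list of MYC targets with ribosome biogenesis had a median of 0.30 in MLL-AF9 against GFP, where no member passed the limma test, and of -0.54 in L-GMP against GMP. With an estimated correlation its adjusted p was 0.662 in the first and 0.0703 in the second. The macrophage gene Adgre1 had a log2 change of -1.22 in the first and of 3.12 in the second. Neither difference between the experiments was tested.

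Sample titles describe the CMP as low and the GMP as high for CD34. The Cd34 transcript read 9.57 in CMP and 8.94 in GMP on the log2 scale (difference 0.62, limma adjusted p = 0.117), and it was lower in MEP than in GMP (by limma, -2.67). Other genes followed the names, with Elane (-4.04) and Fcgr3 (-4.04, adjusted p = 1.65e-13) lower in CMP than in GMP by limma. The CMP titles also say FCR+, and Fcgr3 was at the floor on 2 of the 4 CMP arrays. The other Fc receptor gene looked up, Fcgr2b, had a mean level above the floor in CMP and above its level in HSC.

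For counts of called genes, the samples were regrouped at random into groups of the same size. With 3 against 3 arrays 10 splits exist, too few for a share under 0.05. For MLL-AF9 against GFP only the real split, 1 of the 10, gave 2 genes, against a highest other of 0. The overlap of both experiments (10 of 10 splits, 0 against 0 by limma) faces the same limit, and so do the blocked count (1 of 4 splits, 126 against 0) and the response of the program genes (1 of 10 splits). For that response camera gave 5.31e-08, while the smallest value of the other splits was 3.74e-05 and their median was 0.0117. A camera p under 0.05 at the preset correlation was thus common among arbitrary groupings of these arrays.

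For the sorted experiment only the real split, 1 among those run, gave as many genes, for each count. The median of the other splits was 0 for each count. Every other split put arrays of different sorts into the same group, which widens the spread within groups. These splits therefore cannot decide whether a count, that of the program genes included, arose by chance. Among 100 splits each, L-GMP gave 2825 genes against GMP (highest other 922), 3976 against HSC (3041) and 3357 against CMP (1322), HSC gave 3469 against GMP (2951) and 1132 against CMP (837), and 93 program genes were higher in L-GMP (43). L-GMP against MEP gave 3803 (highest other 152 in 84 splits), HSC against MEP 2772 (433 in 56 splits), CMP against GMP 1413 (1 in 35 splits) and MEP against GMP 2314 (1368 in 35 splits).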
